A study of Homo sapiens with 2 samples.

How the data were processed

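Poly(A) RNA of TF-1 cells was sequenced from 1 sample with an empty vector and 1 sample with a vector holding primary miR-200a, per the labels. The authors deposited 1 gene table in the form that Cufflinks tools write, with an FPKM, a lower and an upper bound and a status per library, per the file headers. The FPKM values are relative to transcript length and to a library total that the authors' tools chose. The submitters' processing notes name TopHat, Bowtie2, Cufflinks and the hg19 build, without versions; the gene annotation, the confidence level of the bounds and whether counting used strand are not given in the sources used here. Genes that overlap on opposite strands are therefore uncertain. No p-value or call of the authors was used here.

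The table has 23284 rows. In 10 rows the estimate failed in at least 1 library and 8 of these were listed at 0 in 1 library, among them PRKDC, RCC1 and CAPN1; these 10 rows were left out. A further 97 rows had a low-data status and were kept. Rows that shared 1 of 2 duplicated symbols were summed, and 28 rows carried a date in place of a symbol, left as they were. The FPKM lay outside its own deposited bounds in 310 rows of the empty vector library and 313 of the miR-200a library, among them many short RNA genes and near-identical copies. Short RNA genes made up 66.0% and 60.6% of the summed FPKM, where a few reads on a very short gene suffice for a large value. Locus starts in the table count from 0 and are given here from 1; a locus can span several overlapping genes.

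Depth is not stated. In single-exon olfactory receptor genes FPKM steps were whole reads, within 0.05 read, for 36 of 36 and 29 of 29 genes when the length was reduced by 198 bases and the totals were 20000000 and 21200000 fragments. The most frequent ratio of the empty vector to the miR-200a value among 2269 genes under FPKM 0.3 was 1.06, for 360 genes, which is the ratio of those totals. The deposited bounds are the only error used for single genes, and they cannot cover differences between cultures.

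The log2 ratio was log2((FPKM + 1)/(FPKM + 1)), miR-200a over empty vector, for genes at FPKM 1 or more in at least 1 library. With 1 library per group there was no test; genes were counted at a 2-fold difference, and the deposited bounds were compared for overlap. For each of 34 fixed gene lists the median log2 ratio of members at FPKM 1 or more, given for 5 or more such genes, was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Lists outside the central 95% are described as lower or higher. This describes the 2 libraries and not the conditions.

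For site matching, the longest annotated 3′ UTR per gene came from GENCODE 29, which is on another build than the table, so only names, sequences, lengths and GC content were taken from it and no coordinates. A gene was classed by its best match to the miR-200a-3p seed: an 8mer, a 7mer-m8 (CAGTGTT) or a 7mer-A1 (AGTGTTA). Controls were 299 shuffles of that 7mer without CpG and the sites of other microRNAs.

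Before the data were examined, the groups, the size rule, the gene lists, the site test and the rule for named genes were set: the 12 genes with the highest and the 12 with the lowest log2 ratio at FPKM 5 or more, 24 genes of interest (miR-200a targets, blood transcription factors, globins and receptors), up to 4 members with the largest absolute ratio per described list, and the miR-200a locus. Of the genes of interest, 1 is not reported here. CA1, SLC4A1, HBD, HBE1, AHSP, TRIB3, CALR, ITGA2B and the examples in the closing section were chosen after their values were seen. So was the count without short RNA genes, with the 12 and 12 genes it names. The adjustment that compares sites within strata of expression and 3′ UTR length (10 by 10) was corrected after a simulation showed that it shrank a known effect, when the first real value had been seen.

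Alternatives were the pseudocount, the minimum FPKM, 2 other scalings of the libraries, the treatment of repeated symbols, the size rule, unmatched random lists, shorter 3′ UTRs, fewer site classes and, added after seeing the data, leaving out short RNA genes or genes outside their own bounds, keeping failed estimates, and sites in genes at FPKM 20 or more. List percentiles were recomputed with new random lists under these settings, a step also added after seeing the data. The procedure was tested on simulated libraries of 12191 genes. In these, 98% of genes changed 3-fold and 100% of those changed 5-fold passed the 2-fold rule, and 0 unchanged genes did. Of 200 lists without a shift, 10 fell outside the central 95%. Genes varied independently in the simulation, so this count does not cover lists whose genes move together. A site effect of -0.1, put into the finished log2 ratios, was recovered as -0.0989, against 0.001 with none put in. This checks the arithmetic of the adjustment, not whether a site effect would stand out from library noise. The count of 0 unchanged genes holds for the simulated noise only. It gives no rate of false calls for the real libraries, since 1 library per group leaves the spread between cultures unknown. In the real libraries the standard deviation of the log2 ratio was 3.35 for short RNA genes and 0.286 for other genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.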

Results

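The data were 2 RNA libraries from TF-1, a human erythroleukaemia cell line that depends on cytokine for growth and was kept here in GM-CSF. The cells of 1 library carried an empty expression vector, and those of the other carried a vector with the primary sequence of microRNA 200a (miR-200a). Poly(A) RNA was sequenced on a Proton instrument, and the deposited table gave FPKM (fragments scaled to transcript length and library total) with a lower and an upper bound for each gene in each library. The labels state overexpression of miR-200a in TF-1 cells, so the comparison asked which transcripts differed when the microRNA was supplied. Each group had 1 library, so no difference below has a replicate check and no p-value is given. The values behind FPKM pointed to about 20000000 normalising fragments in the empty vector library and 21200000 in the miR-200a library, so that FPKM 1 of a 2000-base transcript stood for about 36.04 and 38.2 reads. Log2 ratios are miR-200a over empty vector on the log2(FPKM + 1) scale, which understates differences of genes near or below FPKM 1.

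Most genes had similar levels in both libraries. Among 12321 genes other than short RNA genes at FPKM 1 or more in at least 1 library, 95.5% lay within 1.5-fold and the median log2 ratio was -0.01. By 2-fold or more, 82 of these genes were higher in the miR-200a library and 31 were lower. The deposited bounds of the 2 libraries did not overlap for 106 higher and 28 lower genes. With the 459 short RNA genes (microRNA, small nucleolar RNA and similar) included, the counts were 178 higher and 167 lower of 12780. Of those short RNA genes, 159 were listed at 0 in 1 library. A few reads on a very short gene can give a large FPKM, but the reads of these genes were not examined. Across genes, which are not independent replicates, Pearson's r was 0.944 with the short RNA genes and 0.989 without them.

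**Figure D1:**
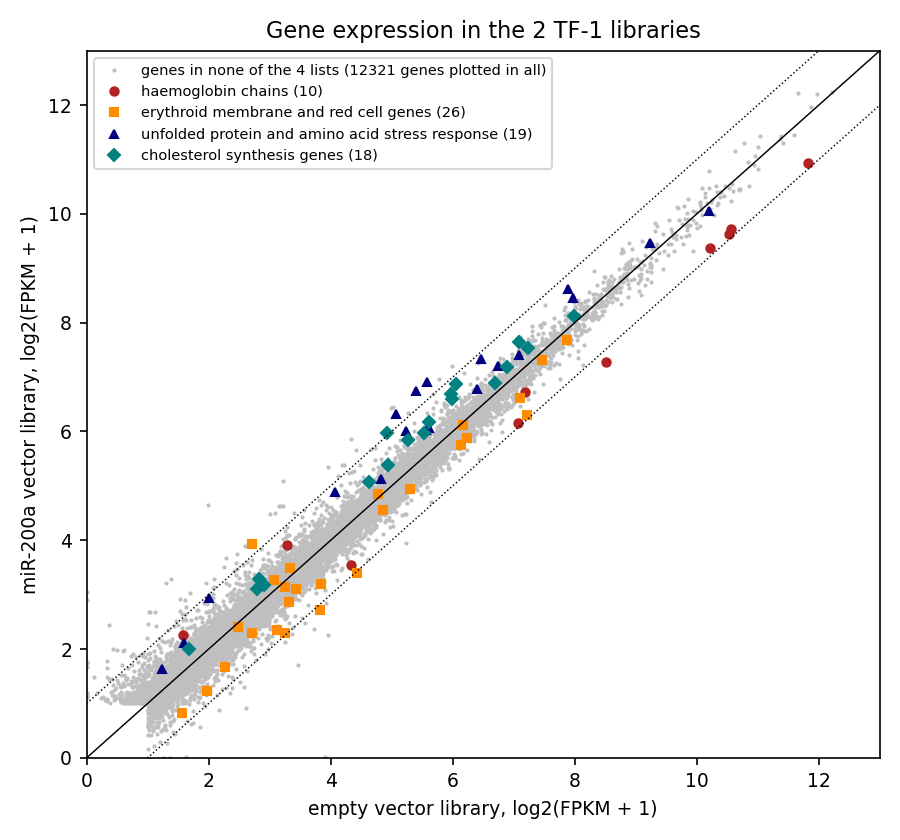
Each point is a gene, with log2(FPKM + 1) in the empty vector library on the horizontal axis and in the miR-200a library on the vertical axis, short RNA genes left out; the solid line marks equal values and the dotted lines a 2-fold difference on this scale. In the haemoglobin list 8 of 10 genes (7 of 9 globins and the chaperone AHSP) lie below the line of equal values, and 18 of 18 cholesterol synthesis genes lie above it.

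The supplied microRNA itself was not readable from these libraries. Its own gene, MIR200A (hg19, chromosome 1, 1103243 to 1103332), was listed at 0 in the empty vector library and at FPKM 27.7 in the miR-200a library, but that FPKM lay above its own deposited upper bound of 3.76. In the miR-200a library 76 microRNA genes had an FPKM at or above that value, and 89 had one in the empty vector library. The neighbouring MIR200B and MIR429 were listed at 0 in both. Mature microRNA carries no poly(A) tail, so these libraries did not measure it.

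Published targets of miR-200a did not differ as a group, and THRB was the exception among those named in advance. THRB, a thyroid hormone receptor (chromosome 3, 24158645 to 24541502), was at FPKM 0.884 with bounds of 0.524 to 1.25 in the empty vector library and 0.254 with bounds of 0.0914 to 0.411 in the miR-200a library. That was 3.48-fold lower in FPKM, from levels under FPKM 1 in both. On the FPKM + 1 scale its log2 ratio was -0.59, which falls short of the 2-fold rule. PDCD4, a tumour suppressor that restrains translation (chromosome 10, 112631553 to 112679124), was at FPKM 41.6 and 35.4, a log2 ratio of -0.23, and its bounds of 30.3 to 53 and 25.7 to 45.2 overlapped. The transcription repressors ZEB1 and ZEB2 had log2 ratios of 0.01 and -0.18, beta-catenin (CTNNB1) 0.05 and the NRF2 inhibitor KEAP1 -0.15. Over the 27 of 38 published targets at FPKM 1 or more, a count that leaves out THRB, 16 were lower and 11 higher, with a median log2 ratio of -0.04 at percentile 26.7 of random lists. The members with the largest absolute ratios were DDIT4 (236 to 394 FPKM, 0.74), the transferrin receptor TFRC (430 to 323, -0.41), RASSF2 (12.8 to 9.56, -0.39) and MACC1 (1.10 to 0.691, -0.31).

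Haemoglobin and red-cell genes were lower in the miR-200a library. The haemoglobin list had 10 measured genes, 9 globins and the alpha-globin chaperone AHSP (FPKM 145 and 104). Of the globins 7 were lower, and of the list 8, with a median log2 ratio of -0.85 (95% interval over genes -0.92 to 0.62) at percentile 0 of random lists matched on expression. Zeta-globin (HBZ; chromosome 16, 202854 to 204504) was at FPKM 363 and 155, theta-globin (HBQ1) at 133 and 69.9, the gamma-globins HBG2 at 3615 and 1957 and HBG1 at 1194 and 662, and the alpha-globins HBA2 at 1477 and 796 and HBA1 at 1514 and 846. Beta-globin (HBB) was at 19.1 and 10.7. The bounds were apart for HBZ and overlapped for the other 9 genes of the list. The adult delta-globin HBD (2.0 and 3.77) and the embryonic epsilon-globin HBE1 (8.75 and 14) were the 2 globins that were higher. HBA1 and HBA2, and HBG1 and HBG2, are near-identical pairs whose reads can be split arbitrarily, and the FPKM of HBA1, HBG1, HBG2 and HBZ lay outside its own deposited bounds in at least 1 library.

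The same direction held for membrane, blood group and late red-cell genes, of which 22 of 26 were lower, with a median log2 ratio of -0.38 (95% interval over genes -0.66 to -0.16) at percentile 0. The fatty acid and thrombospondin receptor CD36 was at FPKM 13.2 and 5.61, beta-spectrin (SPTB) at 20.7 and 9.49, and glycophorin E (GYPE, a gene with near-identical relatives) at 8.50 and 3.91. Carbonic anhydrase 2 (CA2) went the other way, from 5.57 to 14.2, while carbonic anhydrase 1 (CA1) was at 148 and 77.9. The bounds did not overlap for CD36, SPTB, CA1, CA2 and the anion exchanger SLC4A1 (2.94 and 1.33).

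In contrast, the regulators of red-cell development were not shifted as a list. Over the 17 measured genes of that list, mostly transcription factors and receptors, the median log2 ratio was -0.05 at percentile 35.4, with 7 higher and 10 lower. GATA1, the master erythroid factor, was at FPKM 256 and 254, and MYB at 54.0 and 51.4. KLF1, the activator of adult globin and other red-cell genes, was at 264 and 163 (-0.69) and the basic helix-loop-helix factor LYL1 at 266 and 177 (-0.59). The erythropoietin receptor EPOR was at 24.9 and 18.5 (-0.41). RHAG, a membrane protein that the list also holds, was at 78.8 and 59.2 (-0.41). Bounds overlapped for KLF1, LYL1, EPOR and RHAG. GATA2 was at 302 and 377 (0.32), TAL1 at 52.5 and 63.7 (0.28), RUNX1 at 20.2 and 18.2 (-0.14) and SPI1 at 148 and 141 (-0.06). Haem synthesis and iron genes had a median of -0.10 at percentile 7.77, with 12 of 20 lower. ALAS2, the first enzyme of haem synthesis in red cells (chromosome X, 55035488 to 55057497), was at FPKM 36.6 and 14.5 with bounds apart, ALAD at 38.7 and 25.6, UROD at 1172 and 1767, and HMOX1, which breaks haem down, at 15.6 and 21.5.

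**Figure D2:**
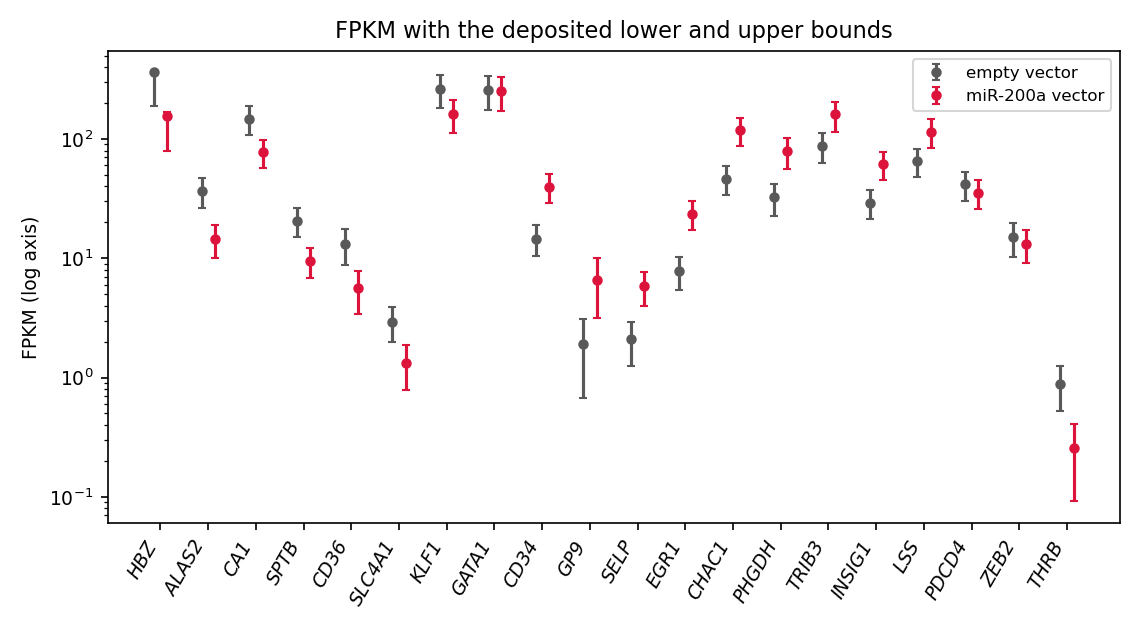
FPKM on a log axis of 20 genes in the empty vector library (grey) and the miR-200a library (red); the bars run to the deposited lower and upper bounds, and the FPKM of HBZ in the empty vector library lies above its own upper bound. The bounds are apart for ALAS2 (36.6 and 14.5) and CD34 (14.6 and 39.8) and overlap for KLF1, GATA1, PDCD4 and ZEB2.

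Genes of the unfolded protein and amino acid stress response were higher in the miR-200a library. Of 19 genes 18 were higher, with a median log2 ratio of 0.50 (95% interval over genes 0.39 to 0.87) at percentile 100. The pro-apoptotic factor DDIT3 was at FPKM 41.2 and 107, the glutathione-degrading enzyme CHAC1 at 46.6 and 119, the serine synthesis enzyme PHGDH at 32.5 and 78.6, and ATF3 at 3.04 and 6.63. Bounds were apart for CHAC1, PHGDH and TRIB3 (87.7 and 161). Calreticulin (CALR) was the member that was lower, at -0.14. Cholesterol synthesis genes were higher in 18 of 18 cases, with a median of 0.45 (0.30 to 0.59) at percentile 100. The sterol sensor INSIG1 was at FPKM 29.2 and 62.0 and lanosterol synthase (LSS) at 65.1 and 115, both with bounds apart, and HMGCS1 was at 62.0 and 102 and MVD at 62.8 and 96.1.

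Early-response genes were also higher, as were stem cell and megakaryocyte genes, but with no minimum FPKM the last 2 lists fell back among random lists. CD34, the surface marker of blood progenitors (chromosome 1, 208059883 to 208084683), was at FPKM 14.6 and 39.8 with bounds apart. Over the 6 measured stem and progenitor genes the median was 0.33 at percentile 99.3, and 0.05 at percentile 86.4 with no minimum FPKM, with CD38 at 0.231 and 1.09, KIT at 1.41 and 2.04 and GATA2 as given above. Among 14 megakaryocyte and platelet genes 10 were higher, with a median of 0.23 at percentile 99.9. That median was 0.10 at percentile 97.1 with no minimum FPKM and 0.71 with a minimum of 5. The platelet glycoproteins GP9 (1.90 and 6.58) and GP6 (19.5 and 37.4), P-selectin (SELP, 2.09 and 5.83) and neurogranin (NRGN, 51.6 and 92.3) led this list with bounds apart, while ITGA2B, the main integrin of the lineage, was at 340 and 365. Immediate early genes had 12 of 16 higher and a median of 0.39 at percentile 100, which was 0.59 and 0.20 with pseudocounts of 0.1 and 5, still above random lists. They included EGR1 (7.87 and 23.7), FOS (0.890 and 2.81), ATF3 and DUSP1 (1.01 and 2.14). The 95% intervals of the medians of these 3 lists included 0, since some members went the other way.

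Another 5 lists lay above random lists, but the 95% interval of each median over genes included 0, and 4 of the 5 fell back among random lists under some setting. The mast cell, basophil and eosinophil list had 7 of 10 genes higher and a median of 0.31 (-0.17 to 0.71) at percentile 99.9, or 0.09 at percentile 83.1 with a minimum FPKM of 5, with tryptase TPSB2 at FPKM 2.48 and 4.92, histidine decarboxylase HDC at 1.59 and 3.23 and TPSAB1 at 1.85 and 3.07, but the IgE receptor chain MS4A2 at 1.40 and 0.463. Granulocyte genes had 6 of 8 higher and a median of 0.29 (-0.53 to 0.90) at percentile 98.8, or 0.10 at percentile 96.8 with a pseudocount of 5. Their largest ratios came from genes near the floor, AZU1 (0.35 and 1.52) and MMP9 (0.373 and 1.19). Of 7 mesenchymal genes 5 were higher, with a median of 0.34 (-0.32 to 2.07) at percentile 99.8, which became 0.01 at percentile 60.2 with no minimum FPKM. N-cadherin (CDH2) was at 0.287 and 4.4 with bounds apart, TWIST1 at 2.0 and 3.94, SPARC at 16.3 and 26.6 and SNAI1 at 18.2 and 23.4. Targets of p53 had 10 of 15 higher and a median of 0.21 (-0.03 to 0.45) at percentile 99.9, or 0.09 at percentile 95.8 with no minimum FPKM, led by FDXR (28.9 and 43.1). Cytokine receptor and STAT target genes had 15 of 24 higher and a median of 0.11 (-0.03 to 0.33) at percentile 98.9, led by IL3RA (2.44 and 4.26). ID1 in that list was lower, at 69.6 and 46.9, and the GM-CSF receptor chains CSF2RA (7.62 and 10.2) and CSF2RB (112 and 110) had overlapping bounds, outside which the FPKM of CSF2RA itself lay.

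Interferon-induced and mitotic genes were lower. Of 22 interferon-induced genes 17 were lower, with a median of -0.22 (95% interval over genes -0.58 to -0.03) at percentile 0, and the antiviral genes IFIT1 (8.49 and 3.37), OASL (3.67 and 1.40) and ISG15 (215 and 124) led, while OAS1 was at 0.471 and 1.31. Of 22 mitotic (G2/M) genes 21 were lower, with a median of -0.17 (-0.25 to -0.09) at percentile 0.16, the cyclin-dependent kinase CDK1 at 54.7 and 39.8 and cyclin A2 (CCNA2) at 36.5 and 28.6. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 12 of 15 lower and a median of -0.17 at percentile 1.0. HIST1H3D (27.8 and 16.3) and HIST1H3B (83.8 and 125) went opposite ways. Targets of Wnt and beta-catenin had 8 of 12 lower and a median of -0.20 (-0.35 to 0.16) at percentile 1.19, but -0.04 at percentile 19.0, among random lists, with no minimum FPKM, with SP5 at 1.48 and 0.753 and LEF1 at 6.81 and 4.85, but TNFRSF19 at 0.825 and 2.72.

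The remaining lists stayed within the central 95% of random lists. DNA replication (G1/S) genes had a median of -0.06, apoptosis regulators 0.01, CDK inhibitors 0.11, targets of the antioxidant factor NRF2 0.06, NF-kB and inflammatory genes 0.07, nuclear-encoded respiratory chain genes 0.02, microRNA processing genes 0.00 and housekeeping genes 0.01. Cytosolic ribosomal protein genes had 26 of 32 lower and a median of -0.12 at percentile 3.54, which moved to 0.33 when short RNA genes were left out. Hypoxia and glycolysis genes had a median of 0.11 with 14 of 15 higher, and the angiogenic factor VEGFA was at FPKM 50.1 and 103 with bounds apart. Heat shock genes had a median of 0.00, although the near-identical HSPA1A (19.7 and 37.8) and HSPA1B (24.2 and 50.2) were higher. For the 8 measured lymphoid genes the median was 0.11, and CD7 (10.1 and 2.26) and CD3D (1.2 and 4.35) went opposite ways. Monocyte genes had a median of -0.06, with lysozyme (LYZ) at 14.2 and 24.1. Only 4 of 18 epithelial genes were measured, too few for the list rule, with the keratins KRT8 at 29.9 and 50.9 and KRT18 at 137 and 212. No mitochondrially encoded gene was in the table used here. In all 6 of 32 lists lay below and 10 above the central 95% of random lists, where 1.6 would fall outside if genes varied independently. Genes of a list can move together between cultures, so more than 1.6 may fall outside with no effect of the vector. Several lists also share members. Of those 16 lists, 9 stayed on the same side of the random lists under every alternative run: haemoglobin, red-cell, interferon, mitotic, histone, stress, cholesterol, immediate early and cytokine genes.

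**Figure D3:**
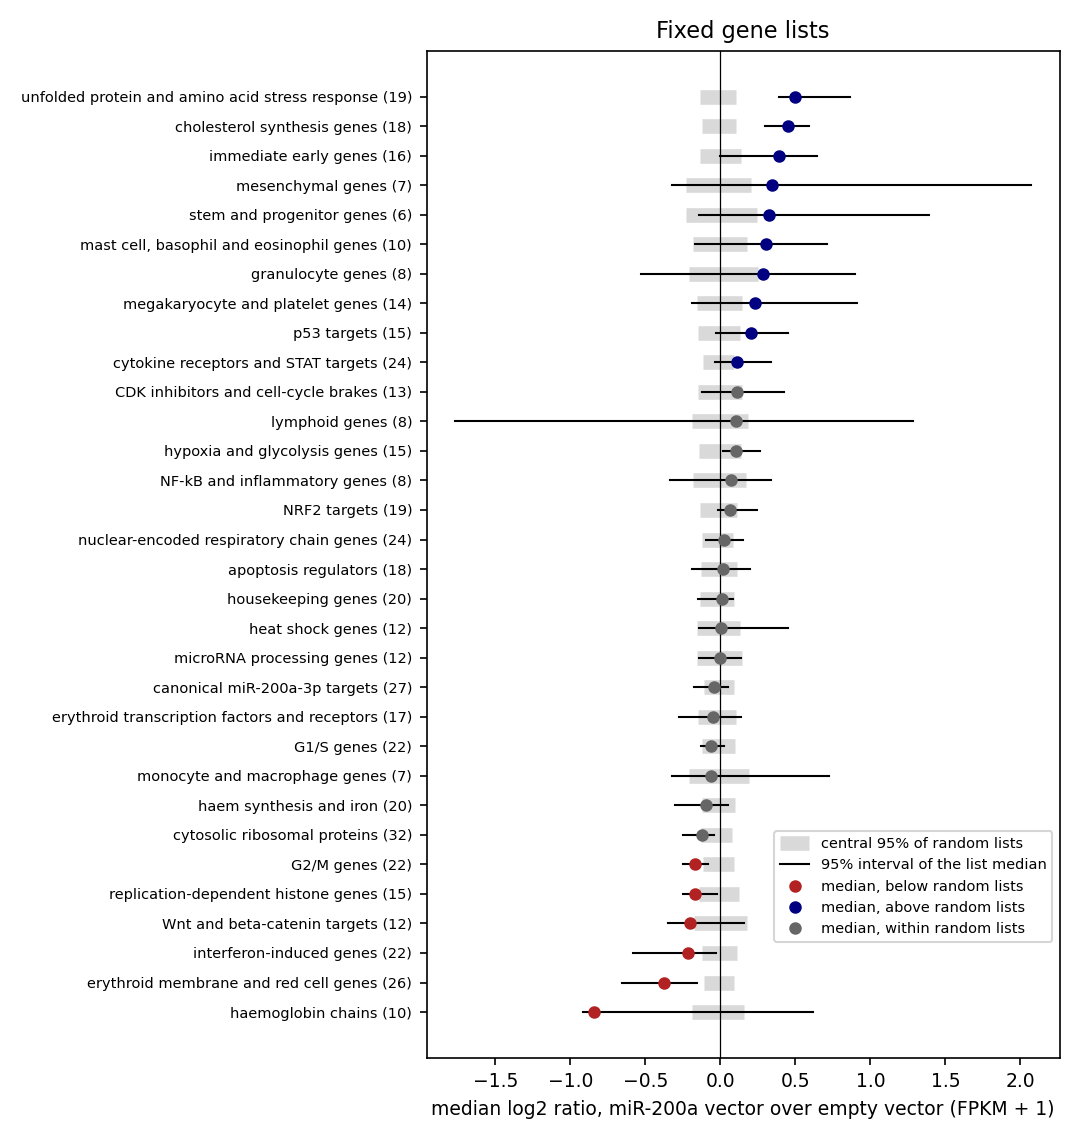
Points are the median log2 ratios (miR-200a vector over empty vector, FPKM + 1) of the 32 lists with 5 or more measured genes, whose number stands in parentheses; black lines are 95% order-statistic intervals of the median over genes, and grey bars the central 95% of 10000 random lists matched on expression. The haemoglobin list, which includes AHSP, is lowest at -0.85 and the unfolded protein and amino acid stress response is highest at 0.50.

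By the size rule for single genes, the 12 genes with the highest and the 12 with the lowest log2 ratio at FPKM 5 or more were all short RNA genes listed at 0 in 1 library, such as MIR3687 (0 and 397) and SNORD43 (500.3 and 0), which a few reads on a very short gene can give. With short RNA genes left out, a choice made after the values were seen, the retinoic acid-binding protein CRABP1 (chromosome 15, 78632666 to 78640572) was at FPKM 2.97 and 24.1, 8.13-fold higher in the miR-200a library. The LIM-domain protein FHL1 was at 1.46 and 8.34, the neuropeptide ADCYAP1 at 1.60 and 8.76, KCTD15 at 8.32 and 33.2, AKAP2 at 7.07 and 21.4 and the metal-binding metallothionein MT2A at 19.3 and 56.9, each with bounds apart, although the FPKM of MT2A in the miR-200a library exceeded its own upper bound. PAGE5 (1.18 and 5.41) had overlapping bounds. On the lower side, the T-cell surface protein CD7 was at 10.1 and 2.26, 4.46-fold lower and with bounds apart. The telomerase RNA TERC (14.6 and 3.77), NBL1 (5.15 and 0.891), C4orf48 (12.2 and 4.2), SPATA25 (5.00 and 1.45), HIST1H3G (10.9 and 4.60) and LOC100128071 (9.31 and 3.87) had overlapping bounds. The other genes on the lower side were ALAS2, HBZ, IFIT1 and CD36 and, with an uncertain value, RPL21, which has many processed copies. Values of the read-through genes CORO7-PAM16, PPAN-P2RY11 and INO80B-WBP1 and of FLJ39739 on the higher side are uncertain too, since their reads can be assigned to overlapping or repeated genes.

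Genes whose 3′ UTR carries a match to the miR-200a-3p seed did not differ as a group from genes without one. A 3′ UTR was found for 11274 of the 12321 genes (91.5%), and 2848 of them held an 8mer or 7mer site. Their median log2 ratio less that of the 8426 genes without a site was 0.002. The median itself, -0.007, lay at percentile 59.4 of random lists matched on expression and 3′ UTR length. These lists were drawn from all 11274 genes, those with a site included, which pulls such percentiles towards the middle. Genes with an 8mer, the strongest class (582 genes), differed by 0.001, those with a 7mer-m8 as best site (1673) by 0.006 and those with a 7mer-A1 (593) by -0.012. Their medians lay at percentiles 49.7, 79.3 and 6.57 of such lists. Genes with a site had longer 3′ UTRs (median 2858.5 against 904 bases). Compared within strata of expression and 3′ UTR length, the differences were -0.004 for any site, -0.004 for the 8mer, -0.0002 for the 7mer-m8 and -0.02 for the 7mer-A1. ZEB1, ZEB2, KEAP1, RUNX1 and THRB had an 8mer, PDCD4, KIT and CSF2RB a 7mer-m8 and CTNNB1 a 7mer-A1, while GATA1, KLF1, MYB, TAL1, ALAS2 and the haemoglobin genes HBA1, HBA2, HBB, HBG1 and HBG2 had none of the 3.

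**Figure D4:**
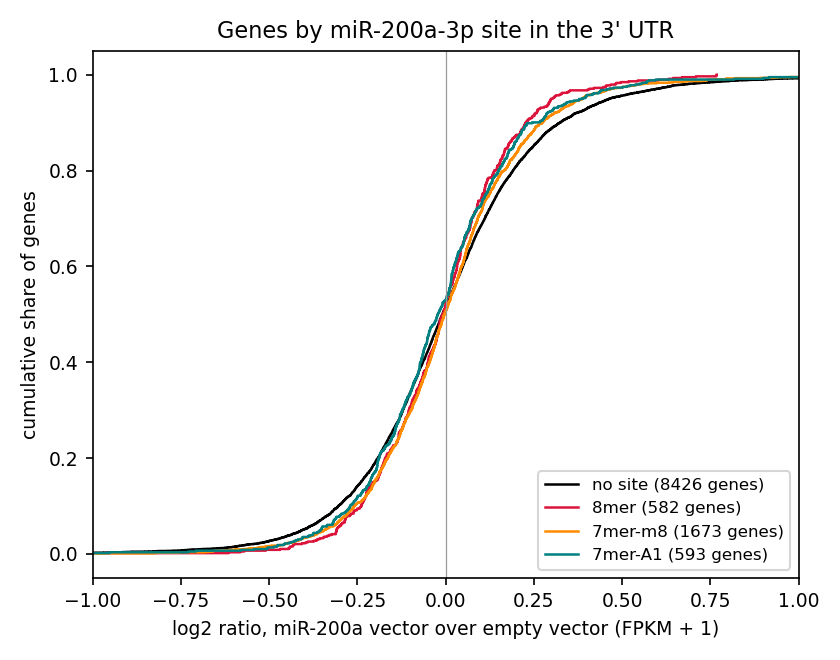
Cumulative share of genes (vertical axis) against the log2 ratio of miR-200a vector over empty vector on FPKM + 1 (horizontal axis, drawn from -1 to 1), by the best miR-200a-3p site in the 3′ UTR. The curves of 582 genes with an 8mer, 1673 with a 7mer-m8 and 593 with a 7mer-A1 cross that of 8426 genes without a site close to 0.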

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

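The short RNA, outside-bounds, failed-estimate and FPKM 20 settings were chosen after seeing the data. No paired analysis was possible because each group had 1 library, and leaving out a library in turn was not possible for the same reason. The comparison with a list of genes called by the authors was not run. Stem and granulocyte lists had under 5 genes at a minimum FPKM of 5 and gave no value there. Of the 16 lists outside the central 95% of random lists, 9 stayed on the same side under every alternative run; percentiles under the alternatives were computed after the medians were seen. Recomputed list medians stayed within the interval over genes of their own list, but these intervals are wide for short lists; 3 lists inside the random range changed sign (CDK inhibitors, microRNA processing and monocyte genes). Scaling to the median or the upper quartile shifted all log2 ratios by about 0.01.

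The count of higher genes, 178, became 292 with a pseudocount of 0.1, 113 with a pseudocount of 5, 466 at 1.5-fold, 90 at 3-fold and 82 without short RNA genes. The count of lower genes, 167, became 391 at 1.5-fold and 31 without short RNA genes. Pearson's r, 0.944, was 0.895 and 0.963 with the pseudocounts of 0.1 and 5, 0.970 with no minimum FPKM, 0.902 with a minimum of 5, 0.989 without short RNA genes and 0.956 without genes outside their own bounds. Spearman's rho, 0.944, was 0.952 and 0.931 with no minimum and a minimum of 5, 0.987 without short RNA genes and 0.958 without genes outside their bounds. With no minimum FPKM, which adds genes near 0, the percentile became 86.4 for stem and progenitor, 97.1 for megakaryocyte, 96.0 for mast cell, 60.2 for mesenchymal, 95.8 for p53 and 19.0 for Wnt genes. With a minimum of 5 it was 83.1 for mast cell and 7.08 for Wnt genes; Wnt genes were at 3.01 with a pseudocount of 0.1 and granulocyte genes at 96.8 with a pseudocount of 5. Ribosomal protein genes moved from percentile 3.54 to 0.85 against unmatched random lists, 1.90 with no minimum, 1.68 without genes outside their own bounds and 0.33 without short RNA genes. The difference between genes with and without a site, 0.002, was 0.012 for 3′ UTRs of at most 3000 bases, within a range of 0.001 to 0.012 over 12 alternatives. The other thresholds count more or fewer genes by construction; otherwise the cause was not tested. Depth limits genes under about FPKM 1 and all short RNA genes.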

Other observations

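The tests of shared globin reads and of the state of the cultures were chosen after the result was seen. So was the test of sites in most of the lower red-cell genes. The other tests were set before their own values were seen. The patterns in red-cell, stress and cholesterol genes were themselves named from the results. Tests of these patterns, including those on transcript length and GC content, were therefore not planned before the data were examined. Genes in the next paragraph were chosen after their values were seen.

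Single genes outside the lists stood out, and no set test was run on them. ESAM, an adhesion molecule of endothelium and platelets, was at FPKM 31.6 in the empty vector library and 86.8 in the miR-200a library, the receptor TIE1 at 40.02 and 70.1 and the VEGF receptor KDR at 0.399 and 1.43, each with bounds apart. The metallothionein genes MT1X (9.60 and 21.6) and MT1G (0.256 and 2.42) had overlapping bounds.

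Haemoglobin and red-cell genes were lower in the miR-200a library. A trend with transcript length or GC content is argued against as the whole cause, since the median of the haemoglobin list (9 globins and the chaperone AHSP), -0.85, lay at percentile 0 of random lists matched on both, whose central 95% was -0.23 to 0.19. Reads shared between near-identical globins are argued against as the whole cause, since the 52 haemoglobin, haem and red-cell genes other than HBA1, HBA2, HBG1 and HBG2 had a median of -0.30, also at percentile 0, with 38 lower. For those 4 genes themselves it stays open: a split of reads within a pair leaves its sum as it was, and the sums had log2 ratios of -0.87 (HBA1 and HBA2) and -0.88 (HBG1 and HBG2), but the summed bounds of the 2 libraries overlapped. For direct miR-200a-3p sites the list of erythroid factors and receptors was taken in as well, which added KLF1 and LYL1. Such sites may act in single genes such as CD36, RHD and SLC4A1, but 15% of the 20 genes lower by 0.5 or more (3 genes) held a site. Sites in the 3′ UTR are therefore not a candidate explanation for most of them. Random sets matched on 3′ UTR length held a median of 3 genes with a site as well (central 95% 0 to 5, percentile 63.1 with ties split). These values show no excess of sites, but with 20 genes and a range that reaches 0 they cannot exclude that sites act in a few of them. An indirect effect of miR-200a and a different state of the single cultures both stay open.

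Amino acid stress and cholesterol synthesis genes were higher together. The median of 0.47 over 37 genes lay at percentile 100 of random lists matched on transcript length and GC content, which argues against such a trend as the whole cause. A different state of the single cultures at harvest, such as medium use or density, cannot be told apart from an effect of miR-200a, because each group had 1 library.

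Genes with a miR-200a-3p site differed little from genes without one, by 0.002 before and -0.004 after adjustment for expression and 3′ UTR length. The difference of genes with the 7mer, compared within strata of expression and 3′ UTR length, was 0.003 and lay at percentile 77.9 of 299 shuffled 7mers, so 3′ UTR composition could account for a value of that size with no action of the microRNA. Sites of microRNAs that were not supplied gave percentiles of 5.35 (miR-200b, miR-200c and miR-429), 99.0 (let-7) and 100 (miR-451a), and the other arm, miR-200a-5p, gave 4.35. These sites differ from the shuffles in base composition, so the shuffles are not a matched reference for them. The miR-451a site also holds a CpG and lay in 201 genes, while each shuffle lay in 475 or more. A small share of transfected cells, weak processing of the primary sequence or action on translation stay open, since none was measured in these libraries.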
